A study of Mus musculus with 16 samples.

How the data were processed

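The values used were the deposited array values, taken as the authors gave them, on a log2 scale. The submitters' notes name Affymetrix Expression Console, and its version, its algorithm and the array annotation build are not given in the sources used here. Values ran from 2.29 to 18.6, and 4365 of them (0.946%) lay above 16, the log2 ceiling of a 16-bit scanner, so the scale may be stretched and folds with it. The sorted values of any array differed from those of another by at most 0.346, so the arrays had been normalized against each other before deposit, by a method not given in the sources used here. The series text also names another odour, bourgeonal; the title and every sample label name cigarette smoke, and the labels were followed. The deposited total RNA was 50 to 100 ng per sample, and the mice were 7 to 12 weeks old and of both sexes.

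Of 28846 probe sets, 19572 carried one gene symbol, 2634 carried none and 6640 were controls. Each gene was represented by its probe set with the highest mean, which left 19505 genes; 55 genes had more than one probe set. The mouse annotation used (GRCm38.p6) served only for gene names and the order of neighbouring genes. A gene was called at or below the level of the vomeronasal receptors where its group mean did not exceed the mean over that group's arrays of their 95th percentile among vomeronasal receptors (6.14 to 6.78 per array), a level chosen after the data were seen. Where one group lay there, the bound given is the distance of the other group from the mean of this group with values below that level raised to it.

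Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) to all 16 arrays with 4 group means and 5 contrasts. These were smoke against vehicle in GFP+ cells, the same in GFP- cells, the difference between these as a ratio of fractions, and GFP+ against GFP- cells in vehicle and in smoke mice. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, or over a list alone where so stated, at 0.05. The fractions of the same replicate number came from the same pool, and their residuals correlated with r of 0.22, 0.091, 0.093 and 0.13 in smoke pools and 0.21, 0.082, 0.045 and 0.20 in vehicle pools. Groups, contrasts, thresholds, gene lists and most alternatives were chosen before the data were examined. With 200 genes shifted in simulation, a log2 difference of 1 was recovered for 80% in GFP+ cells, 94% in GFP- cells and 52% in the ratio. Each rate rests on 50 genes, and false calls made up 6.67%, 7.37% and 1.46% of the simulated calls. The simulated noise was independent between arrays, without effects of pool or cell makeup, so recovery in the real data may be lower.

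Lists of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 24 lists with at least 5 measured genes. The lists were odorant receptors (1080 genes), trace amine-associated receptors (15), vomeronasal receptors (319), GC-D and Ms4a neuron genes (13), mature (21) and immature (17) olfactory sensory neurons, activity-raised (7) and activity-lowered (3) olfactory neuron genes and immediate early genes (25). Response lists were aryl hydrocarbon receptor targets (8), NRF2 targets (18), inflammation (20), unfolded protein and integrated stress response (14), heat shock proteins (9) and p53 targets and apoptosis (13). Cell type lists were sustentacular (16), horizontal basal (10), globose basal and proliferation (14), microvillar and ionocyte (15), gland and respiratory epithelium (20), olfactory ensheathing (8), immune (20), red blood (3) and endothelial and stromal cells (13). The rest were ribosomal proteins (71, taken by symbol prefix and so including ribosomal protein kinases such as Rps6ka5), oxidative phosphorylation (84), sex-linked genes (3) and mitochondrially encoded genes (0 measured).

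The genes named were fixed by rule. S100a5 and Omp were always named. For each comparison the 10 largest rises and the 10 largest falls were named among genes with an adjusted p of at most 0.05 and groups that did not overlap (for the ratio, among those with such an adjusted p). Up to 15 odorant receptors each way were named by smallest p, 5 for the sort comparisons, and from each list up to 4 genes past the all-gene threshold, or else the 2 with the smallest p. Other genes are named where the text says so or as members of a counted group. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.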

Results

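Gene expression was measured on 16 Clariom S mouse arrays in 4 groups of 4. The animals were S100a5-tauGFP mice, which make green fluorescent protein (GFP) under the control of S100a5, a calcium-binding protein gene of olfactory sensory neurons whose expression follows recent activity. The 24 mice formed 8 pools of 3, and each spent 40 h alone in a chamber of clean air flowing at 3.1 L per min. From 26 h on, 4 pools received pulses of cigarette smoke odour and the other 4 received pulses of filtered air (vehicle), each pulse lasting 10 s and returning every 20 min. The olfactory mucosa of each pool was dissociated and its cells were sorted into a GFP+ and a GFP- fraction, so every pool gave an array of each. Most olfactory sensory neurons express a single odorant receptor gene, and the sort therefore asks which receptors belong to neurons that the odour activated. Array medians were 7.87 to 7.96 on the log2 scale in GFP+ cells and 8.19 to 8.29 in GFP- cells, and correlations across genes between arrays of one group were 0.988 to 0.995. Replicates are pools of mice, so the p-values measure the spread between arrays of different pools, and the number of arrays limits the precision. The main fit did not pair the GFP+ and GFP- arrays of a pool. Its p-values for the sort and the ratio therefore do not measure the spread of differences within pools. The Y-linked genes Uty, Eif2s3y and Kdm5d were low in replicate 1 of both exposures (Uty 3.52 to 4.07 on 3 of these 4 arrays and 6.57 in smoke GFP- replicate 1, against 10.6 to 12.1 in replicates 2 to 4), so each exposure had 1 pool with little Y-linked signal.

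S100a5 was highest in smoke GFP+ cells and lowest in vehicle GFP- cells. Its values were 16.8 to 17.1 in smoke GFP+, 16.4 to 16.5 in vehicle GFP+, 15.5 to 16.1 in smoke GFP- and 14.9 to 15.5 in vehicle GFP- cells (n = 4 each). The GFP+ cells exceeded the GFP- cells by 1.21 in vehicle mice (SE 0.14, adjusted p = 2.88e-06) and by 1.15 in smoke mice (SE 0.14, adjusted p = 6.45e-06). Smoke arrays exceeded vehicle arrays by 0.56 in GFP+ cells and by 0.62 in GFP- cells (SE 0.14 each). In all 4 of these comparisons the groups did not overlap. All GFP+ values of S100a5 and some in smoke GFP- cells lay above the ceiling of a 16-bit scanner, so the size of its differences is uncertain. The exact two-sided permutation p was 0.0286 for smoke against vehicle, the lowest that 4 arrays against 4 can give. For GFP+ against GFP- cells, swapped within pools, it was 0.125, the lowest that 4 pools can give. The adjusted p over all genes for smoke against vehicle was 0.364 in GFP+ and 0.179 in GFP- cells. Omp, which encodes the olfactory marker protein of mature olfactory sensory neurons, differed by 0.04 between smoke and vehicle GFP+ cells (exact two-sided permutation p = 0.0571) and by 0.02 between the GFP- groups (exact p = 0.571). It differed by 0.10 and 0.12 between GFP+ and GFP- cells of vehicle and smoke mice (exact p = 0.125 within pools each). None of the Omp differences passed over all genes, with adjusted p of 0.288 and above. Omp lay at 18.1 to 18.3 on every array, near the array maxima, all above 18.5, and above the ceiling of a 16-bit scanner, so a probe set near saturation cannot show that Omp did not change.

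**Figure D1:**
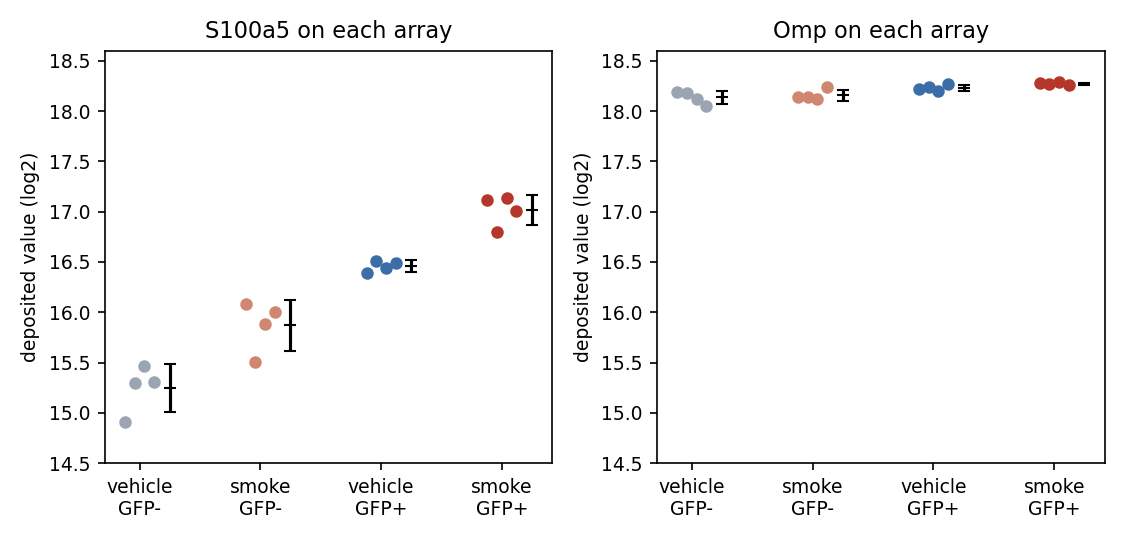
Deposited log2 values of S100a5 (left) and Omp (right) on each of the 16 arrays, with the mean and SD of each group of 4 beside the points. S100a5 lies at 16.8 to 17.1 in smoke GFP+ cells and at 14.9 to 15.5 in vehicle GFP- cells.

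In GFP+ cells, smoke exposure raised a small set of odorant receptors and trace amine-associated receptors. The largest rise was that of Olfr1278, at 3.97 (SE 0.32, n = 4, adjusted p = 1.78e-05), from 7.06 in vehicle to 11.03 in smoke GFP+ cells, a 15.7-fold change. Olfr736 rose by 3.24 (SE 0.29, adjusted p = 4.84e-05), Olfr750 by 3.23 (SE 0.32, adjusted p = 1.11e-04) and Olfr878 by 3.03 (SE 0.32, adjusted p = 2.19e-04). Taar2, a member of a separate family of olfactory amine receptors, rose by 2.51 (SE 0.38, adjusted p = 0.00890). In limma, 20 genes rose and 1 fell among 19505, with 936 at an unadjusted p below 0.05. Without smoke GFP+ replicate 2, 13 rose and 1 fell. Of the 21 genes 16 were odorant receptors, 15 higher and Olfr1152 lower, at -1.83 (SE 0.32, adjusted p = 0.0348). The other 5, named after their values were seen, included Taar2, Taar7d (1.53, SE 0.24, adjusted p = 0.00976), Taar7f (1.46, SE 0.19, adjusted p = 0.00432). The remaining ones were Pir (0.94, SE 0.14, adjusted p = 0.00890), which encodes pirin, an iron-binding nuclear protein, and the gene model Gm3411 (0.76, SE 0.12, adjusted p = 0.0146). For each odorant receptor named for GFP+ cells, all 4 smoke arrays lay on one side of all 4 vehicle arrays.

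Among the 1080 odorant receptors measured, 40 rose and 5 fell when adjusted over the list alone. The number that fell was 14 without smoke GFP+ replicate 3, 13 without vehicle GFP+ 1, 3 without smoke GFP+ 1 or vehicle GFP+ 4, and 15 in a fit to the GFP+ arrays alone. With a replicate block 64 rose and 20 fell. The risers spanned 0.61 to 3.97 with a median of 1.40, and 3 of them had a vehicle mean at or below the level of the vomeronasal receptors, which this tissue should lack. Besides those above, the risers with the smallest p included Olfr1277 (2.85), Olfr1178 (2.69), Olfr1313 (2.38), Olfr1182 (2.27), Olfr153 (2.18), Olfr484 (2.15), Olfr1184 (1.75), Olfr923 (1.74), Olfr16 (1.63), Olfr1307 (1.41) and Olfr1087 (1.39). The 4 other receptors that fell were Olfr520 (-1.01), Olfr370 (-0.98), Olfr1349 (-0.96) and Olfr24 (-0.94). The family as a whole did not pass a test of a shift in one direction: its median was -0.05, its mean 0.02, and camera gave a downward direction with an adjusted p of 0.836. Smoke GFP+ replicates 2 and 4 carried more sustentacular cell signal than the other GFP+ arrays, with list means of 11.1 and 11.4 against 10.5 to 10.7. Without smoke pools 2 and 4, an alternative added after the data were seen, 20 receptors and 8 genes passed. Olfr1278, Olfr736, Olfr750, Olfr878 and Olfr1313 kept their calls with each array left out in turn and without both pools. On the 2 smoke pools left, other named genes did not pass over all genes, while their changes stayed near those of the full fit. These were Olfr1178 (2.82, adjusted p = 0.0889), Olfr1182 (2.52, 0.113), Olfr1277 (2.81, 0.122), Olfr1152 (-1.99, 0.148), Taar2 (2.51, 0.154) and Olfr153 (2.22, 0.400). Taar7f (1.27, 0.113) and Taar7d (1.29, 0.355) had somewhat smaller changes. Adjusted over the list alone, Olfr16 (0.0530), Olfr1349 (0.0778), Olfr370 (0.136) and Olfr520 (0.266) were also lost.

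**Figure D2:**
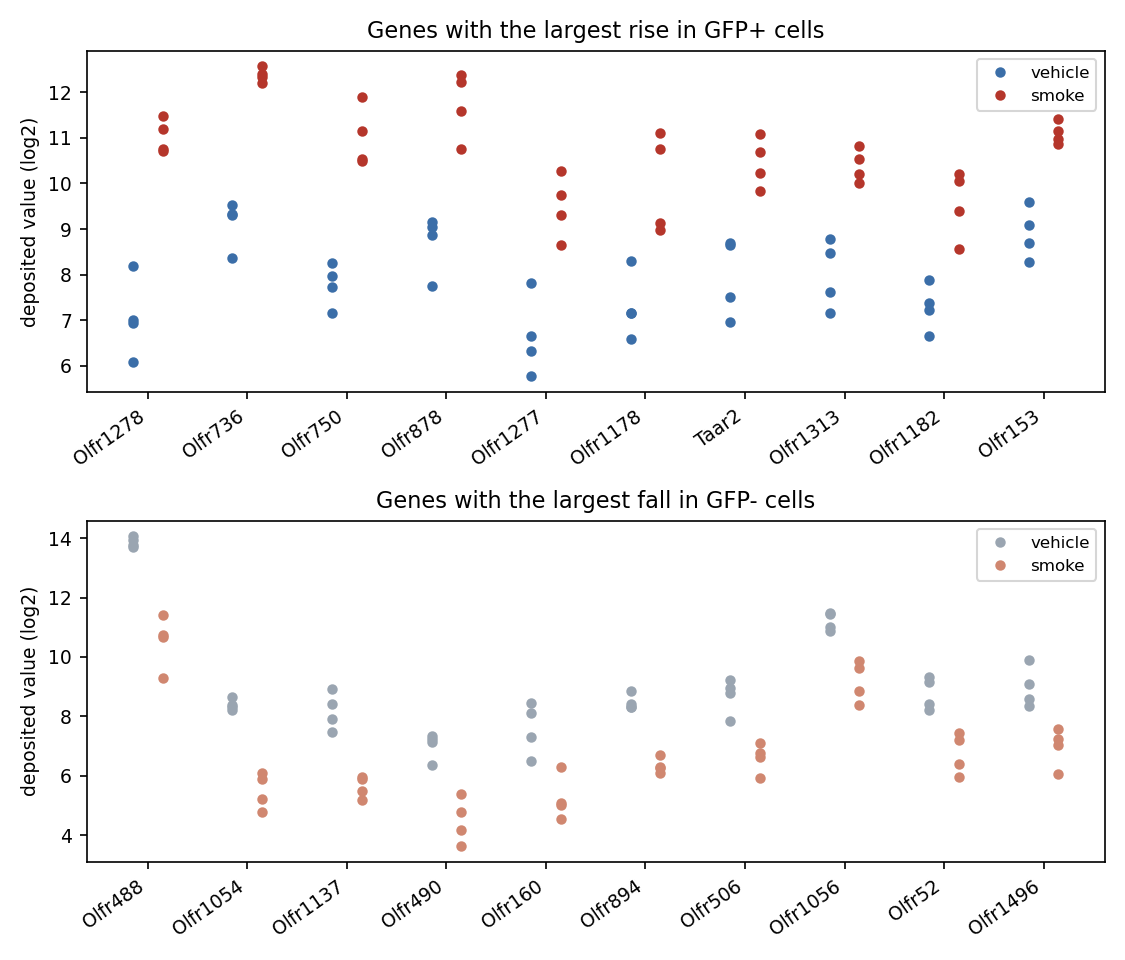
Deposited log2 values on each of 4 smoke and 4 vehicle arrays for the 10 genes with the largest rise in GFP+ cells (top) and the 10 with the largest fall in GFP- cells (bottom), 1 point per array. All 4 smoke arrays lie above all 4 vehicle arrays in the top panel and below them in the bottom panel.

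The calls of several named GFP+ genes rested on single arrays, given here as the adjusted p without each. Taar7d was lost without smoke replicate 2 (0.0565), and Olfr1178 without smoke 2 (0.0710) or vehicle 1 (0.0609), 2 (0.0510) or 4 (0.0525). Olfr1182 was lost in every case but smoke 4 and vehicle 3 (highest 0.150, without vehicle 1), Olfr153 in every case but vehicle 3 (highest 0.171, without vehicle 1) and Olfr1152 in every case but smoke 2 and vehicle 2 (highest 0.155, without smoke 4). Adjusted over the list alone, Olfr520 was lost without smoke 2 or 4 or vehicle 1 or 4 (highest 0.0913), Olfr1349 without smoke 1 or 4 or vehicle 3 or 4 (highest 0.0975) and Olfr370 in every case but vehicle 2 (highest 0.112).

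NRF2 targets, the antioxidant and detoxification genes switched on by the transcription factor NRF2, rose together in GFP+ cells. Their median change was 0.16 over 18 genes (camera adjusted p = 1.08e-05, and adjusted p = 0.0122 with an estimated correlation). None of the 18 passed over all genes in limma, and 5 rose when adjusted over the list alone, among them Nqo1, a quinone reductase (0.56, SE 0.13, adjusted p = 0.00858), and Me1, the cytosolic malic enzyme (0.59, SE 0.16, adjusted p = 0.0107). Leaving out each array in turn gave medians of 0.14 to 0.20, and with an estimated correlation the call was lost without vehicle replicate 2 (adjusted p = 0.0502). The sustentacular cell list, markers of the supporting cells of the epithelium, had a median of 0.40 (adjusted p = 9.57e-06, and adjusted p = 0.434 with an estimated correlation), with 0 of 16 genes past either threshold. Gstm1, a glutathione transferase on both lists, differed by 0.58 and Cbr2, a carbonyl reductase, by 0.63. Without smoke pools 2 and 4, left out for their high sustentacular signal, the sustentacular median was 0.02. The NRF2 median was then 0.11 (adjusted p = 0.00124, and adjusted p = 0.119 with an estimated correlation).

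The trace amine-associated receptors rose as a set by camera (adjusted p = 0.00553, and adjusted p = 0.411 with an estimated correlation). Their median was -0.04 and their mean 0.34: 3 of 15 rose and 12 did not pass over all genes. Taar4 fell within the list (-0.89), and with each array left out in turn the median lay between 0.01 and 0.15. Activity-raised neuron genes had a median of 0.19 (adjusted p = 0.0261, and adjusted p = 0.411 with an estimated correlation), with S100a5 (adjusted p = 0.00729) and Sema7a, a semaphorin of olfactory axons (0.47, adjusted p = 0.00977), higher when adjusted over the list alone. Aryl hydrocarbon receptor targets had a median of 0.10 (adjusted p = 0.0466, and adjusted p = 0.274 with an estimated correlation), and Nqo1 alone among 8 passed within the list (adjusted p = 0.00381). Oxidative phosphorylation genes had a median of 0.06 (adjusted p = 0.0338, and adjusted p = 0.931 with an estimated correlation), with 0 of 84 past the threshold. Single arrays ended these 4 set calls. The trace amine receptor call was lost without vehicle replicate 3 (0.0688), and the activity-raised call without smoke 1 (0.162), smoke 3 (0.160) or vehicle 3 (0.136). The aryl hydrocarbon receptor call was lost without smoke 2 or 4 or vehicle 1, 2 or 3 (highest 0.171), and the oxidative phosphorylation call without smoke 3 or 4 or vehicle 1, 2 or 3 (highest 0.850). The other lists did not pass. Ribosomal proteins had an adjusted p of 0.0661, immune cells 0.220, GC-D and Ms4a neuron genes 0.290, and immature neurons 0.501. Inflammation, globose basal cells and microvillar cells had 0.535 each, and vomeronasal receptors 0.751. Mature neurons, heat shock proteins, p53 targets, glands, ensheathing cells and endothelial and stromal cells had 0.831 each. The unfolded protein response had 0.836, immediate early genes 0.899 and horizontal basal cells 0.930. The sign of the median, mean and test direction was not the same for immediate early genes, horizontal basal cells and glands. The lists with 3 measured genes had medians of -0.14 (activity-lowered), -0.18 (red blood cell) and -0.13 (sex-linked), and no gene of theirs passed.

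In GFP- cells, more odorant receptors fell than rose after smoke among those that passed, while 35% of all 1080 lay below 0 and the family median was 0.16. Olfr488 fell by 3.34 (SE 0.30, n = 4, adjusted p = 6.79e-05), from 13.9 in vehicle to 10.5 in smoke GFP- cells. Olfr894 fell by 2.13 (SE 0.25, adjusted p = 0.00128), Olfr506 by 2.10 (SE 0.27, adjusted p = 0.00252), Olfr1056 by 2.03 (SE 0.25, adjusted p = 0.00206), Olfr52 by 2.02 (SE 0.32, adjusted p = 0.0111) and Olfr1496 by 2.0 (SE 0.31, adjusted p = 0.0111). Olfr1054, Olfr1137, Olfr490 and Olfr160 ended at or below the level of the vomeronasal receptors, so their falls are given as bounds, of at least 2.13, 1.92, 0.753 and 1.30 (adjusted p = 6.79e-05, 0.0418, 0.00151 and 0.0111). In limma, 3 genes rose and 22 fell among 19505, with 1115 at an unadjusted p below 0.05, and all 22 were odorant receptors. The 3 that rose were Olfr798 (1.02, SE 0.19, adjusted p = 0.0418), Pir (0.88, SE 0.14, adjusted p = 0.0152) and the glutathione peroxidase gene Gpx5 (adjusted p = 0.0330), whose means in both groups were at or below the level of the vomeronasal receptors.

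When adjusted over the list alone, 19 odorant receptors rose and 55 fell in GFP- cells. The number that rose was 9 without smoke GFP- replicate 4, 10 without smoke 1 or vehicle 3, 11 without vehicle 1 and 30 without smoke 3. With a replicate block 55 rose and 68 fell, and at an adjusted p of 0.10 48 rose and 75 fell, so the excess of falls depends on the model. The falls had a median of -1.32, and 10 of the 55 ended at or below the vomeronasal level. Olfr958 (-1.82), Olfr982 (-1.76), Olfr1122 (-1.84), Olfr1135 (-1.70) and Olfr1257 (-1.05) were among those with the smallest p, and Olfr1032 fell by at least 0.710. The rises spanned 0.53 to 1.40 with a median of 0.97. They included Olfr648 (1.31), Olfr33 (1.20), Olfr654 (1.18), Olfr615 (1.14), Olfr651 (1.10), Olfr808 (1.03), Olfr95 (0.97), Olfr1450 (0.84), Olfr544 (0.82), Olfr763 (0.79), Olfr458 (0.78) and Olfr1387 (0.68). Olfr518 and Olfr945 were higher by at least 0.435 and 0.571 over the vomeronasal level. Of the 40 receptors that rose in GFP+ cells, 9 were among the 55 that fell in GFP- cells, against 2.04 expected by chance (one-sided Fisher's exact p = 9.54e-05): Olfr16, Olfr360, Olfr484, Olfr488, Olfr855, Olfr923, Olfr1090, Olfr1161 and Olfr1257. Fisher's test takes the receptors as independent. Both comparisons share one spread per gene, so a receptor of low spread passes more easily in both, and this p may be too small. Of the 40, 33 had a GFP- change below 0 (median -0.44), against 35% of all receptors. Olfr1152 fell in both fractions. With the immune list mean of the GFP- arrays as a covariate, added after the data were seen, 8 receptors rose and 62 fell. Sustentacular signal was not adjusted for in GFP- cells.

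**Figure D3:**
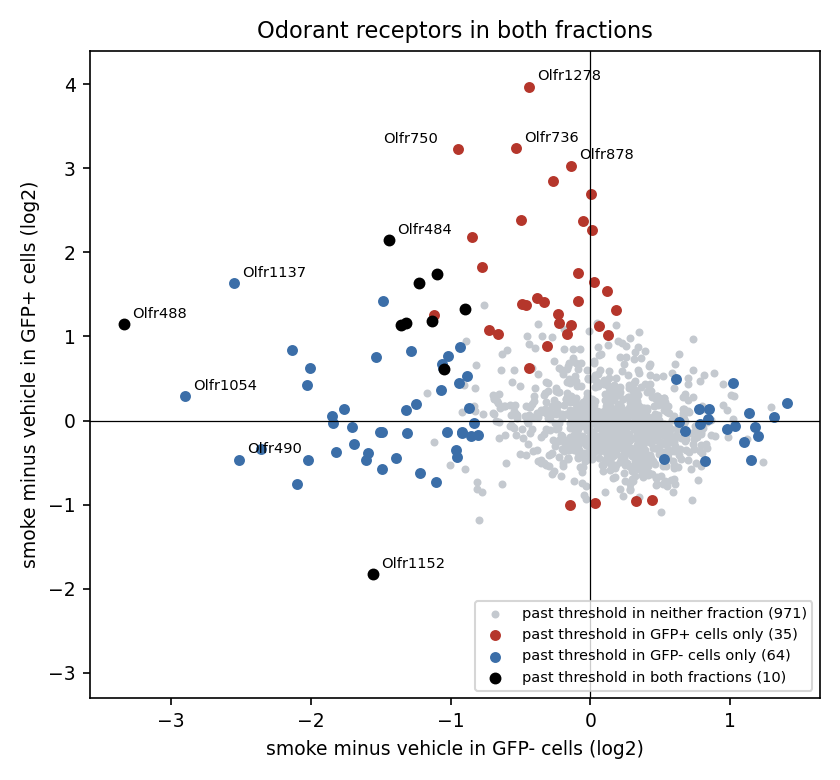
Smoke minus vehicle difference (log2) of each of 1080 odorant receptors in GFP+ cells (vertical) against GFP- cells (horizontal), coloured by the fraction in which it passed the test adjusted over the list alone. 35 receptors passed in GFP+ cells only, 64 in GFP- cells only and 10 in both.

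The number of genes past the all-gene threshold in GFP- cells fell from 25 to 13 without vehicle GFP- replicate 1, 14 without vehicle 2 and 16 without smoke 2, and to 8 in a fit to the 8 GFP- arrays alone. Olfr1137 and Olfr798 were lost without any single array of the 8 (highest adjusted p = 0.216 and 0.172). Gpx5 was lost without smoke 3 (0.0664) or vehicle 1, 2 or 3 (highest 0.126), Olfr160 without smoke 2 (0.0520) or vehicle 2 (0.0514) or 3 (0.0546). Pir was lost without vehicle 1 (0.0782) or 3 (0.0699) and Olfr52 without vehicle 2 (0.0514) or 4 (0.0507). Adjusted over the list alone, 9 of the 15 named risers (Olfr95, Olfr1387, Olfr544, Olfr458, Olfr615, Olfr33, Olfr648, Olfr1450 and Olfr945) were lost without at least 3 of the 8 arrays each (highest adjusted p = 0.107), and the 15 named receptors that fell kept their calls.

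Ribosomal proteins, inflammation genes and 3 cell type lists were lower as sets in smoke GFP- cells, each losing its call with an estimated correlation. Ribosomal proteins had a median of -0.18 (adjusted p = 8.38e-10, and adjusted p = 0.356 with an estimated correlation), immune cells -0.31 (4.13e-07, and adjusted p = 0.286 with an estimated correlation) and gland and respiratory epithelium -0.45 (2.19e-04, and adjusted p = 0.286 with an estimated correlation). Inflammation genes, which share S100a8 and S100a9 with the immune list, had -0.26 (0.00105, and adjusted p = 0.286 with an estimated correlation), and microvillar cells and ionocytes -0.22 (0.00541, and adjusted p = 0.110 with an estimated correlation). No gene of these 5 lists passed over all genes, and Ltc4s, the leukotriene synthase gene, was the only one lower within its list (-0.52, adjusted p = 0.0283). Ribosomal, immune and microvillar sets kept their calls with each array left out, while the inflammation call was lost without vehicle replicate 4 (0.0532) and the gland call without vehicle 3 (0.0967). Medians then ran from -0.23 to -0.09 (ribosomal), -0.55 to -0.18 (immune), -0.29 to -0.14 (microvillar), -0.36 to -0.14 (inflammation) and -0.57 to -0.20 (gland). A regrouping with many gene calls set smoke 1 and 4 and vehicle 1 and 2 against the rest. There the immune median was -0.54 and the inflammation median -0.46. The gland, ribosomal and microvillar medians were -0.27, -0.14 and 0.0076.

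A further 8 sets passed in GFP- cells with adjusted p of 0.0224 to 0.0347, all lost with an estimated correlation and with at least 2 single arrays left out. Activity-raised genes had a median of 0.23 (adjusted p = 0.0224, and adjusted p = 0.286 with an estimated correlation), with S100a5 (adjusted p = 0.00267) and Sema7a (0.46, adjusted p = 0.0112) higher when adjusted over the list alone. The set was lost without smoke 3 (0.0545) or vehicle 4 (0.0696). Trace amine-associated receptors had -0.20 (0.0262, and adjusted p = 0.356 with an estimated correlation), with Taar3 higher (1.10) and Taar7f lower (-0.72) within the list (adjusted p = 0.0142 each). Taar2 (-1.07) and Taar7d (-0.77) were also lower there. The set was lost without smoke 2 or 3 or vehicle 2 (highest 0.324). Odorant receptors had 0.16 (0.0304, and adjusted p = 0.680 with an estimated correlation) and mature neurons 0.08 (0.0304, and adjusted p = 0.619 with an estimated correlation). Both were lost without smoke 1 or 4 or vehicle 3, the first also without vehicle 1 and the second without vehicle 4 (highest 0.916 and 0.386). Immediate early genes had -0.15 (0.0262, and adjusted p = 0.455 with an estimated correlation) and were lost without smoke 1, 3 or 4 or vehicle 2 (highest 0.224). Globose basal cells had -0.21 (0.0262, and adjusted p = 0.619 with an estimated correlation) and were lost without smoke 1 or 4 or vehicle 1, 3 or 4 (highest 0.831). Horizontal basal cells had -0.23 (0.0304, and adjusted p = 0.286 with an estimated correlation) and were lost without smoke 2, 3 or 4 or vehicle 2 or 4 (highest 0.105). Endothelial and stromal cells had -0.06 (0.0347, and adjusted p = 0.286 with an estimated correlation) and were lost without smoke 2 or 4 or vehicle 3 (highest 0.396). The other 11 tested lists had adjusted p of 0.101 to 0.796. NRF2 targets were among them (median 0.06, adjusted p = 0.101), with Nqo1 higher within the list (0.53, SE 0.13, adjusted p = 0.0140), as were aryl hydrocarbon receptor targets (0.638), sustentacular cells (median -0.13, 0.103) and p53 targets (0.796). Among the latter the cell cycle inhibitor gene Cdkn1a was higher within the list (0.55, SE 0.14, adjusted p = 0.0155). The lists with 3 measured genes had medians of 0.16 (activity-lowered), -0.59 (red blood cell) and 0.54 (sex-linked). For ensheathing cells the median was above 0 and the mean and test direction below.

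The ratio of GFP+ to GFP- cells, compared between smoke and vehicle mice, joins both fractions into one test of a receptor's shift towards the GFP+ gate. Olfr488 had the largest rise of this ratio, at 4.49 (SE 0.42, 4 pools against 4, adjusted p = 1.89e-04). It was followed by Olfr1278 at 4.42 (SE 0.45, adjusted p = 2.90e-04) and Olfr750 at 4.18 (SE 0.45, adjusted p = 3.73e-04). Next were Olfr736 at 3.78 (SE 0.41, adjusted p = 3.73e-04), Olfr484 at 3.59 (SE 0.41, adjusted p = 5.89e-04), Taar2 at 3.58 (SE 0.53, adjusted p = 0.00546), Olfr878 at 3.17 (SE 0.45, adjusted p = 0.00366) and Olfr1277 at 3.12 (SE 0.57, adjusted p = 0.0318). Olfr1137 and Olfr1054, at or below the vomeronasal level in smoke GFP- cells, rose by at least 3.56 and 2.43 (adjusted p = 0.00977 and 6.83e-04). In limma, the ratio rose for 33 genes and fell for 1 of 19505, with 1114 at an unadjusted p below 0.05. Of the 33, 30 were odorant receptors and the other 3 were Taar2, Taar7d (2.3, SE 0.33, adjusted p = 0.00482) and Taar7f (2.18, SE 0.27, adjusted p = 0.00127). The single fall was that of Olfr24, at -1.39 (SE 0.27, adjusted p = 0.0473). S100a5 differed by -0.07 (SE 0.20, adjusted p = 0.987), so its ratio between the fractions did not pass a test of change.

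When adjusted over the list alone, the ratio rose for 73 odorant receptors and fell for 25. The number that fell was 7 without smoke pool 1, 54 without smoke pool 3, 13 without smoke pool 4 and 12 without vehicle pool 3 or 4. It was 54 with each pool of mice as a block, which pairs its GFP+ and GFP- arrays, and 90 rose there. A group at or below the vomeronasal level was involved in 8 of the 73 and 1 of the 25. The rises spanned 1.02 to 4.49 with a median of 1.84, and the falls -1.67 to -0.68 with a median of -1.10. Of the 73, 35 also rose in GFP+ cells, 35 also fell in GFP- cells, 9 of these did both, and 12 passed in neither fraction alone. Further receptors whose ratio rose included Olfr894 (2.97), Olfr16 (2.86), Olfr923 (2.84), Olfr360 (2.50), Olfr1056 (2.45), Olfr777 (2.11), Olfr1257 (1.66) and Olfr1032 (at least 1.47). Further receptors whose ratio fell included Olfr679 (-1.67), Olfr49 (-1.47), Olfr523 (-1.44), Olfr651 (-1.36), Olfr63 (-1.30), Olfr544 (-1.30), Olfr1349 (-1.29), Olfr1364 (-1.23), Olfr1361 (-1.08), Olfr971 (-1.06), Olfr366 (-0.99), Olfr17 (-0.96) and Olfr55 (-0.74), and Olfr518 fell by at least 0.910. Without smoke pool 2 the all-gene count was 16, without vehicle pool 2 it was 22, and without both smoke pools 2 and 4 it was 9, with 45 receptors past the list-alone threshold. Without both pools some named genes did not pass over all genes, with changes near those of the full fit: Olfr24 (-1.70, adjusted p = 0.0980), Taar7f (1.96, 0.150), Taar2 (3.77, 0.25), Taar7d (2.14, 0.288) and Olfr1277 (3.19, 0.611). Olfr1137 did not pass either (0.569). Over all genes, Olfr1137 was lost without smoke pool 2 (0.0984) or 4 (0.0598) or vehicle pool 3 (0.0645) or 4 (0.0629), Olfr1277 without all but smoke pool 1 and vehicle pool 2 (highest 0.182) and Olfr24 without all but smoke pools 1 and 4 (highest 0.245). Adjusted over the list alone, the 15 named rises kept their calls without each single pool, as did the falls of Olfr24, Olfr366, Olfr518, Olfr651 and Olfr544, and the other 10 named falls were lost without at least 1 pool each (highest 0.116). Without both smoke pools 2 and 4 the named rises also kept these calls, while 9 named falls lost them: Olfr523, Olfr1361 and Olfr55 (0.0986 each), Olfr17 (0.104), Olfr971 (0.106), Olfr518 (0.127), Olfr651 and Olfr1349 (0.153 each) and Olfr679 (0.211).

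Among the lists, the ratio rose for the trace amine-associated receptors, with a median of 0.17 and a mean of 0.55, 3 of 15 rising (adjusted p = 0.00185, and adjusted p = 0.340 with an estimated correlation). Leaving out each pool moved the median between -0.09 and 0.34. Further sets, of cell types and of other functions, also had higher ratios. These were sustentacular cells (median 0.50, adjusted p = 3.13e-05, and adjusted p = 0.454 with an estimated correlation) and ribosomal proteins (0.24, 1.19e-08, and adjusted p = 0.518 with an estimated correlation). They included gland and respiratory epithelium (0.38, 0.00624, and adjusted p = 0.518 with an estimated correlation) and microvillar cells (0.27, 0.0106, and adjusted p = 0.161 with an estimated correlation). The last were immune cells (0.24, 0.0235, and adjusted p = 0.652 with an estimated correlation), oxidative phosphorylation (0.08, 0.0326, and adjusted p = 0.812 with an estimated correlation) and globose basal cells (0.27, 0.0330, and adjusted p = 0.652 with an estimated correlation). Apart from these 3 and Taar3, whose ratio fell within the list (-1.18), no gene of these lists passed in limma, over all genes or over its list alone. The immune and globose basal calls were both lost without smoke pool 1 or 4 or vehicle pool 4, the first also without vehicle pool 3 (highest 0.260) and the second without vehicle pool 1 (highest 0.467), and the oxidative phosphorylation call without smoke pool 3 or vehicle pool 2 or 4 (highest 0.595). The other 16 tested lists had adjusted p of 0.0746 to 0.996, with odorant receptors at 0.0998 (median -0.22), NRF2 targets at 0.0746 and mature neurons at 0.0912; for heat shock proteins the mean was below 0 and the median and test direction above. The lists with 3 measured genes had medians of -0.30 (activity-lowered), 0.18 (red blood cell) and -0.34 (sex-linked).

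Without odour, the sort itself separated cell types and receptors. In vehicle mice the GFP+ cells held far less RNA of immune cells. Mmp8, a neutrophil collagenase, was lower by -8.30 (SE 0.45, n = 4, adjusted p = 4.25e-10), Ly6c2, a surface antigen of monocytes, by -8.18 (SE 0.37, adjusted p = 6.85e-11). Retnlg, a resistin-like gene of neutrophils, was lower by -8.10 (SE 0.38, adjusted p = 1.03e-10) and S100a8, a calcium-binding protein of neutrophils, by -8.06 (SE 0.38, adjusted p = 1.10e-10). Ly6c1 (-7.96) and Ctse (-7.94) followed, and Hp, Mmp9, Camp and Mrgpra2b were lower by at least 7.56, 6.88, 7.10 and 7.07, their GFP+ means lying at or below the vomeronasal level. The largest rises were odorant receptors, led by Olfr536 at 5.40 (SE 0.22, adjusted p = 2.12e-11), Olfr110 at 4.83 (SE 0.19, adjusted p = 1.75e-11), Olfr481 at 4.78 (SE 0.26, adjusted p = 4.90e-10) and Olfr309 at 4.77 (SE 0.28, adjusted p = 9.03e-10). Olfr1093 (4.75), Olfr372 (4.65), Olfr101 (4.50), Olfr533 (4.42) and Olfr517 (3.75) were also higher, and Olfr613 and Olfr1132 by at least 4.29 and 4.24. Among 1080 receptors, 599 were higher and 220 lower in GFP+ cells when adjusted over the list alone, the lower ones led by Olfr1507 at -6.24 (SE 0.22), Olfr1406 at -5.82 (SE 0.21), Olfr1384 at -5.72 (SE 0.23), Olfr1042 at -4.85 (SE 0.18) and Olfr237 at -3.94 (SE 0.12). The higher receptors had a median of 1.71 (61 with a GFP- mean at or below the vomeronasal level) and the lower ones a median of -2.44 (40 with such a GFP+ mean).

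**Figure D4:**
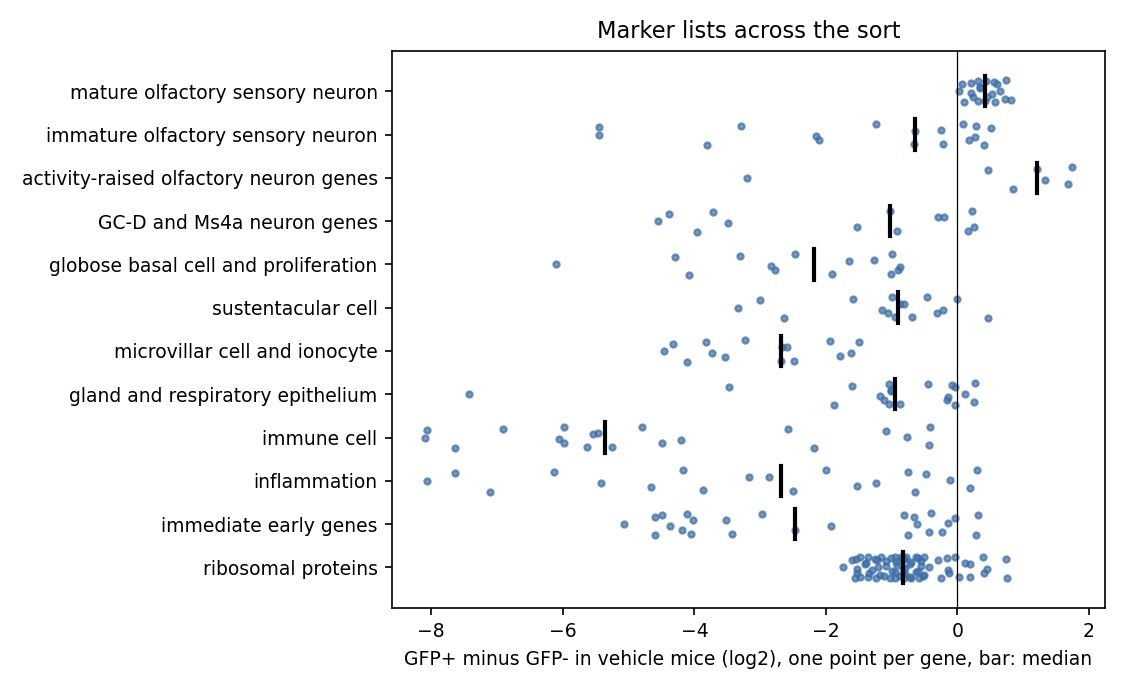
Difference between GFP+ and GFP- cells of vehicle mice (log2, horizontal) for each gene of 12 lists (vertical), 1 point per gene and a bar at the list median. The medians run from -5.36 for immune cells to 1.21 for activity-raised neuron genes, and the ribosomal median is -0.82.

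Over all 19505 genes in vehicle mice, limma called 4728 higher and 2998 lower in GFP+ cells. This split depends on scaling: with arrays centred on their medians, which moves the median of all genes by 0.34, it was 12817 higher and 2269 lower, and with cyclic loess, which moves it by -0.15, it was 2285 higher and 3729 lower. In the immune list 19 of 20 genes were lower (median -5.36, adjusted p = 6.06e-23, and adjusted p = 0.0190 with an estimated correlation), among them the B-cell receptor gene Cd79a, by at least 6.77. All 15 microvillar and ionocyte genes were lower (median -2.68, adjusted p = 2.99e-18, and adjusted p = 1.40e-05 with an estimated correlation), including Hepacam2 (-4.47) and the ionocyte regulator Foxi1 (-3.82). Of 25 immediate early genes 20 were lower (median -2.46, adjusted p = 6.33e-17, and adjusted p = 0.00901 with an estimated correlation), including Btg2 (-5.06), Junb (-4.60) and Nr4a1 (-4.60). This list reads recent activity or the stress of dissociation, and the fractions also differ in cell types. The call therefore does not show that GFP+ neurons were less active. Of 20 inflammation genes 15 were lower (median -2.69, adjusted p = 2.94e-14, and adjusted p = 0.00901 with an estimated correlation), such as Lcn2 (-7.11). GC-D and Ms4a neuron genes had 8 of 13 lower (median -1.03, adjusted p = 1.53e-05, and adjusted p = 0.0219 with an estimated correlation), including the phosphodiesterase gene Pde2a (-3.96) and Ms4a4c (-4.55), a family also known from immune cells. Gucy2d, the GC-D gene (0.16), Cnga3 (0.26) and Emx1 (0.23), named after their values were seen, were not lower. The set call therefore does not show that GC-D neurons were fewer in GFP+ cells. Immature neuron genes had 9 of 17 lower and 1 higher (median -0.64, adjusted p = 1.90e-05, and adjusted p = 0.0301 with an estimated correlation). The largest falls were those of Ablim1 (-5.45), Gng8 (-3.80), Dpysl3 (-3.29) and Cxcr4 (-5.45), a chemokine receptor that leukocytes also carry. Other members, named after their values were seen, went both ways. Gap43 (-2.11) was below 0, while Dcx (0.51), Crmp1 (0.29), Dbn1 (0.26), Stmn4 (0.18) and Tubb3 (0.09) were above it. The set call therefore does not show a fall of immature neuron markers in general.

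Mature olfactory neuron genes were higher in vehicle GFP+ cells, 14 of 21 rising and 0 falling in limma (median 0.41, adjusted p = 2.16e-04, and adjusted p = 0.288 with an estimated correlation), with the phosphodiesterase genes Pde1c (0.82) and Pde4a (0.73) and the exchanger gene Slc24a4 (0.74). Odorant receptors had a median of 0.76 (adjusted p = 1.14e-04, and adjusted p = 0.323 with an estimated correlation), a set call that ended with arrays centred on their medians. Ribosomal proteins were lower in 57 of 71 genes and higher in 3 (median -0.82, adjusted p = 1.60e-20, and adjusted p = 0.137 with an estimated correlation). Globose basal and proliferation genes were lower in 14 of 14, with Mki67 at -6.10 (median -2.18, adjusted p = 6.37e-13, and adjusted p = 0.0546 with an estimated correlation). Sustentacular genes were lower in 11 of 16, with Ezr at -3.34 and Krt18 at -3.01 (median -0.91, adjusted p = 2.32e-06, and adjusted p = 0.224 with an estimated correlation). Gland genes were lower in 8 of 20, with Ltf at -7.43, a lactoferrin gene that neutrophils also express (median -0.95, adjusted p = 2.92e-04, and adjusted p = 0.224 with an estimated correlation). Vomeronasal receptors, near background throughout, had a median of 0.26 (adjusted p = 0.0327, and adjusted p = 0.323 with an estimated correlation), with 45 of 319 higher over all genes and 3 when adjusted over the list alone. The set call ended with quantile scaling or median centring and without vehicle GFP+ replicate 2 (0.0604) or 4 (0.0712) or GFP- replicate 2 (0.0517). NRF2 targets had a median of -0.31 with 5 higher and 7 lower (adjusted p = 0.0454, and adjusted p = 0.147 with an estimated correlation). The call ended with median centring, where the median turned positive, and without GFP+ replicate 2 (0.0836) or 3 (0.0603) or GFP- replicate 1 (0.0571) or 2 (0.0583). The other 10 tested lists had adjusted p of 0.128 to 0.890, and for 5 of them (aryl hydrocarbon receptor targets, unfolded protein response, heat shock, horizontal basal and ensheathing cells) the median was above 0 and the test direction downward. Among them, 6 of 7 activity-raised genes were higher, such as Pcp4l1 (1.75), while Calb2 was lower (-3.20), and 8 of 15 trace amine-associated receptors were higher, such as Taar4 (2.87), and 5 lower, such as Taar2 (-2.79). Of the lists too small for a set test, Slc4a1, the band 3 gene of red blood cells, was lower (-3.71), the activity-lowered gene Epha5 was higher (1.31), and 0 of 3 sex-linked genes passed.

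In smoke mice the sort gave much the same separation. Over all 19505 genes, limma called 3574 higher and 2799 lower in GFP+ cells, against 12173 and 2095 with arrays centred on their medians (a shift of 0.32) and 1803 and 3320 with cyclic loess (a shift of -0.13). Ly6c2 (-8.06, SE 0.37, n = 4, adjusted p = 1.04e-10), Retnlg (-7.87, SE 0.38, adjusted p = 1.64e-10), Mmp8 (-7.69, SE 0.45, adjusted p = 1.18e-09), S100a8 (-7.55, SE 0.38, adjusted p = 2.53e-10) and S100a9 (-7.51, SE 0.31, adjusted p = 3.42e-11) were again among the lowest. Ly6c1, Cd37, Hp, Camp and Mrgpra2b were lower by at least 7.76, 7.18, 7.15, 6.81 and 6.48. The largest rises were Olfr536 (5.34, SE 0.22, adjusted p = 3.42e-11), Olfr424 (5.30, SE 0.36, adjusted p = 7.39e-09), Olfr506 (5.09, SE 0.27, adjusted p = 4.88e-10), Olfr309 (5.02, SE 0.28, adjusted p = 6.50e-10) and Olfr1099 (4.94, SE 0.21, adjusted p = 5.94e-11). Olfr481, Olfr160, Olfr490, Olfr1054, Olfr613 and Olfr521 were higher by at least 5.04, 4.55, 4.36, 4.22, 4.20 and 3.23, their GFP- means lying at or below the vomeronasal level. Among the receptors, 555 were higher (median 1.75, 73 with such a GFP- mean) and 256 lower (median -2.0, 37 with such a GFP+ mean) when adjusted over the list alone, the lower ones led by Olfr1507 (-6.38), Olfr1406 (-5.70), Olfr1384 (-5.35), Olfr1042 (-4.48) and Olfr237 (-3.69). Across genes, which are not independent replicates, the sort differences of vehicle and smoke mice correlated with r = 0.953 over 19505 genes and r = 0.915 over the receptors.

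The lists moved in the smoke sort as follows. Lower in GFP+ cells, and past the threshold with either correlation, were immune cells (17 of 20, median -5.02, adjusted p = 9.40e-23, and adjusted p = 0.0156 with an estimated correlation) and microvillar cells (15 of 15, -2.77, 3.12e-18, and adjusted p = 1.33e-05 with an estimated correlation). The same held for immediate early genes (18 of 25 lower and 1 higher, -2.06, 5.04e-17, and adjusted p = 0.00810 with an estimated correlation) and inflammation (16 of 20 lower and 1 higher, -2.21, 1.22e-14, and adjusted p = 0.00810 with an estimated correlation). It also held for GC-D and Ms4a neuron genes (8 of 13, -1.09, 1.59e-06, and adjusted p = 0.0140 with an estimated correlation) and immature neurons (8 of 17 lower and 1 higher, -0.44, 3.56e-06, and adjusted p = 0.0185 with an estimated correlation). Here too the GC-D and Ms4a call rests on a list with Ms4a genes, a family also known from immune cells. The immediate early gene call has the same limit as in vehicle mice. Ribosomal proteins (50 of 71 lower, median -0.59, 1.18e-15) lost the call with an estimated correlation (adjusted p = 0.238). So did globose basal cells (14 of 14 lower, -1.70, 1.59e-12, then adjusted p = 0.0595), sustentacular cells (5 of 16 lower and 1 higher, -0.39, 0.00348, then adjusted p = 0.411) and glands (5 of 20 lower and 1 higher, -0.10, 0.0312, then adjusted p = 0.421). Higher in GFP+ cells were odorant receptors (median 0.63, 0.00121, and adjusted p = 0.411 with an estimated correlation), mature neurons (9 of 21, 0.28, 0.00148, and adjusted p = 0.396 with an estimated correlation). Also higher were trace amine-associated receptors (8 of 15, 1.02, 0.0119, and adjusted p = 0.309 with an estimated correlation), oxidative phosphorylation (16 of 84 higher and 2 lower, 0.23, 0.0119, and adjusted p = 0.696 with an estimated correlation) and vomeronasal receptors (37 of 319, 0.23, 0.0312, and adjusted p = 0.396 with an estimated correlation). The set calls of the 3 receptor families ended with arrays centred on their medians, that of the vomeronasal receptors also with quantile scaling, and that of the glands with cyclic loess. The vomeronasal call was also lost without smoke GFP+ replicate 1 (0.0762) or 4 (0.0570) or GFP- replicate 2 (0.0644) or 4 (0.0562), the gland call without GFP+ replicate 1 (0.0503) or GFP- replicate 1 (0.0531), and the oxidative phosphorylation call without GFP+ replicate 3 (0.0568) or 4 (0.136) or GFP- replicate 2 (0.0644). The other 9 tested lists had adjusted p of 0.0927 to 0.892, and for 3 of them (unfolded protein response, heat shock and horizontal basal cells) the median was above 0 and the test direction downward. The lists with 3 measured genes had medians of -0.08 (activity-lowered), -2.80 (red blood cell) and -0.39 (sex-linked).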

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

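Single arrays far from the other 3 of their group were looked for among the named genes. Of 874 groups of 4 tested, 36 held such a value, against 43.7 that chance alone would give. Outside the Y-linked genes these were in vehicle GFP- replicate 4 (Gpx5 4.61, Olfr1384 13.0, Pde4a 14.1, Cdk1 7.70, Cd79a 13.6, Atp5k 7.88), vehicle GFP+ replicate 4 (Olfr1093 11.4, S100a9 9.72, Pecam1 6.44), vehicle GFP+ replicate 1 (Olfr517 9.89, Cdk1 3.48, Bpifa1 8.73), smoke GFP+ replicate 1 (Olfr506 12.3, Slc7a11 7.04), vehicle GFP- replicate 1 (Vmn1r44 5.49), smoke GFP+ replicate 3 (Pde2a 8.63, Dpysl3 9.54, Bgn 6.49), smoke GFP+ replicate 2 (Cxcr4 7.78, Cebpd 6.23), vehicle GFP+ replicate 2 (Cyp1a2 9.45, Ndufv3 10.5). Others were in smoke GFP- replicate 1 (Fas 4.996), smoke GFP- replicate 4 (Sec14l3 12.2, Krt8 9.76, Atp5k 7.65), vehicle GFP- replicate 3 (Pou2f3 9.15). The Y-linked values were those of replicate 1: Uty 4.07, Eif2s3y 4.43 and Kdm5d 5.09 in vehicle GFP- cells, 3.52, 4.66 and 4.59 in smoke GFP+ cells, and 3.64, 3.90 and 4.87 in vehicle GFP+ cells.

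Many named receptors differed between exposures in the ratio of GFP+ to GFP- cells. The ratio was higher after smoke for Olfr1278 4.42, Olfr736 3.78, Olfr750 4.18, Olfr878 3.17, Olfr1277 3.12, Olfr1178 2.69, Taar2 3.58, Olfr1313 2.88, Olfr1182 2.25, Olfr153 3.03, Olfr484 3.59. It was also higher for Olfr1307 1.74, Olfr923 2.84, Olfr1087 1.88, Olfr1184 1.84, Olfr16 2.86, Olfr488 4.49, Olfr1054 3.19, Olfr1137 4.19, Olfr490 2.05, Olfr160 2.01. Further receptors were Olfr894 2.97, Olfr506 1.34, Olfr1056 2.45, Olfr52 1.56, Olfr1496 2.63, Olfr958 1.45, Olfr982 1.90, Olfr1032 2.29, Olfr1122 1.81, Olfr1257 1.66, Olfr1135 1.62, Olfr360 2.50, Olfr777 2.11, Taar7d 2.3, Taar7f 2.18. It was lower for Olfr24 -1.39, Olfr1349 -1.29, Olfr651 -1.36, Olfr808 -1.10, Olfr518 -1.63, Olfr1387 -0.81, Olfr544 -1.30, Olfr366 -0.99, Olfr523 -1.44. It was also lower for Olfr63 -1.30, Olfr1361 -1.08, Olfr49 -1.47, Olfr55 -0.74, Olfr1364 -1.23, Olfr679 -1.67, Olfr971 -1.06, Olfr17 -0.96. For the receptors with 1 group at or below the vomeronasal level these differences are not exact: the bounds are at least 3.56 for Olfr1137, 2.43 for Olfr1054, 1.47 for Olfr1032, 0.952 for Olfr160 and 0.286 for Olfr490, and a fall of at least 0.910 for Olfr518. Among 2634 probe sets without a gene name, TC1100001021.mm.2 changed in smoke GFP- cells (-1.50), the only one past the threshold in limma, with 111 at an unadjusted p below 0.05; in GFP+ cells 0 passed, with 114 at an unadjusted p below 0.05.

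The tests of admixed cells, of a looser gate, of NRF2 targets and of Y-linked RNA were chosen only after the results were seen; the regrouping of arrays, the overlap between fractions and the neighbour test were chosen before. The arrays of each comparison were regrouped in all 35 ways, and the real grouping was the only 1 to reach its count in 9 of 10 cases. For GFP+ against GFP- cells only 8 of the groupings keep the pools paired, and the 7 besides the real one gave 0 calls. In the sort comparisons any other grouping mixes both fractions within a group, which widens the spread. Their low counts were thus fixed in advance and cannot speak on chance. For odorant receptors the real count and the highest other were 45 and 30 in GFP+ cells, 74 and 23 in GFP- cells and 98 and 2 in the ratio. They were 819 and 1 in the vehicle sort and 811 and 2 in the smoke sort. The GFP+ grouping with 30 set replicates 1 and 4 of both exposures against replicates 2 and 3 of both. A difference tied to the replicate number may therefore be present among receptors in GFP+ cells. For all genes they were 21 and 3 in GFP+ cells, 34 and 0 in the ratio, 7726 and 1 in the vehicle sort and 6373 and 0 in the smoke sort. In GFP- cells 2 of 35 groupings reached the all-gene count of 25: the other gave 241, setting smoke replicates 1 and 4 and vehicle replicates 1 and 2 against the rest, with 222 of its genes lower and an immune list median of -0.54, so an effect of chance could not be excluded there.

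The rise of odorant receptors in smoke GFP+ cells was weighed against the sort itself. A share of the whole GFP- fraction in the smoke GFP+ arrays is excluded: it could not raise a receptor above its level in GFP- cells, where 25 of the 40 risers lay above it, and the other 15 rose by a median of 1.43 while the immune cell list moved by -0.0878. These values leave open the entry of single cell types, and the sustentacular list had a median of 0.40 in GFP+ cells. A looser GFP+ gate that lets in all kinds of GFP- neurons alike would raise all receptors low in GFP+ cells. The 206 lower by at least 1 at baseline moved by a median of 0.0968 (SE 0.05 over resampled receptors, not pools). Baseline and change were taken from different vehicle arrays. A gate that lets in only neurons just below it need not raise these receptors, so this test cannot exclude it. Movement of neurons from the GFP- into the GFP+ gate fits the 9 receptors both higher in GFP+ and lower in GFP- cells. By chance 2.04 were expected (one-sided Fisher's exact p = 9.54e-05), and such movement may explain part of the change. That p takes receptors as independent and may be too small, since both comparisons share one spread per gene. Of the 40 risers, 31 did not pass a fall in GFP- cells. Still, 33 had a GFP- change below 0 (median -0.44) against 35% of all receptors.

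The rise of NRF2 targets in GFP+ cells came with sustentacular cell signal in smoke replicates 2 and 4. Without these arrays the NRF2 list median was 0.111 instead of 0.165 (adjusted p = 0.00124, and adjusted p = 0.119 with an estimated correlation), so whether sustentacular cell RNA explains the rise of the list as a whole stays open. Of its members, Nqo1 (0.55, SE 0.17), Me1 (0.60, SE 0.20), Txnrd1 (0.38, SE 0.11) and Gclc (0.43, SE 0.15) kept their changes without these arrays. With them the changes were 0.56 (SE 0.13), 0.59 (SE 0.16), 0.34 (SE 0.09) and 0.36 (SE 0.13). The sustentacular median went from 0.40 to 0.02. That drop was largely built in, since these arrays were left out for their high sustentacular signal. For Gstm1, on both lists, the change was 0.209 without these arrays instead of 0.58. As Gstm1 belongs to the list by which the arrays were chosen, its drop cannot decide whether sustentacular RNA is the cause. In GFP- cells the NRF2 list median was 0.0596 (camera adjusted p = 0.101), so a response of the list as a whole in both fractions is likewise open. Of its members, Nqo1 was higher in both fractions when adjusted over the list alone.

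Smoke GFP- replicate 1 carried some Y-linked RNA. Uty was 6.57 on this array against at least 10.6 in replicates 2 to 4, which excludes a wrong label from a pool with male mice. Eif2s3y was 7.88 against 3.90 to 4.66 on the other replicate 1 arrays, and Kdm5d was 5.27 against 4.59 to 5.09, only just above them. The shares of the signal of replicates 2 to 4 were 3.93% for Uty, 6.35% for Eif2s3y and 2.10% for Kdm5d, which may reflect some RNA or cells of a pool with male mice in this array. Leaving this array out, 28 genes passed in GFP- cells instead of 25.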

How the results depend on the processing

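The tests without smoke pools 2 and 4, with makeup covariates and without the array with male-specific RNA were chosen only after the results were seen, and the other alternatives before. With arrays centred on their medians, 15086 genes differed in the vehicle sort and 14268 in the smoke sort, against 7726 and 6373. With arrays of the compared groups alone, 8 genes passed in GFP- cells instead of 25. Array weights gave 76 odorant receptors in GFP+ cells (62 higher and 14 lower) instead of 45 (40 and 5). At an adjusted p threshold of 0.10, 98 receptors passed in GFP+ cells (73 and 25), 123 in GFP- cells (48 and 75) and 162 in the ratio (94 and 68). A replicate block gave 84 receptors in GFP+ cells (64 and 20) and 123 in GFP- cells (55 and 68, against 19 and 55). Whether the replicate number pairs smoke with vehicle pools is not given in the sources used here. The residuals of smoke and vehicle arrays of one number correlated with r of 0.14, 0.077, 0.15 and 0.20 in GFP+ cells, each best matched to its own number. In GFP- cells r was 0.18, -0.071, 0.10 and -0.084, and none was best matched to its own number. Replicate 1 of both exposures was low in Y-linked signal, and replicate 3 had the highest Uty value in all 4 groups. With makeup covariates 13 genes passed in GFP+ cells instead of 21. The covariates were the sustentacular list mean among GFP+ arrays and the immune list mean among GFP- arrays, so each fraction was adjusted for a single list. Without smoke pools 2 and 4, 20 receptors and 8 genes passed in GFP+ cells and 45 receptors and 9 genes in the ratio. Without the array with male-specific RNA, 69 receptors passed in GFP- cells (10 higher and 59 lower) and 85 in the ratio (73 and 12). Leaving out single arrays gave 13 (vehicle GFP- replicate 1) to 28 (smoke GFP- replicate 1) genes in GFP- cells, and single pools 16 (smoke pool 2) to 39 (smoke pool 1) in the ratio. The oxidative phosphorylation median in GFP+ cells ran from -0.00326 without smoke GFP+ replicate 4 to 0.120 without smoke GFP+ replicate 2. No call of a named gene turned direction in any alternative.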

Other observations

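The neighbour test below was chosen before its result was seen, and the comparison of both sorts is a description made after. Between the sorts, 15 receptors passed in opposite directions. In 14 of them the receptor was lower in GFP+ cells of vehicle mice and higher in those of smoke mice, among them Olfr1278 (-3.53 and 0.89), Olfr750 (-3.15 and 1.03), Olfr736 (-1.85 and 1.93), Olfr1137 (-1.27 and at least 2.28) and Olfr484 (-1.15 and 2.44). Olfr294 was another, with all 4 groups at or below the vomeronasal level. Olfr544 did the reverse (0.49 and -0.81). By contrast 495 receptors were higher and 189 lower in both sorts.

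Receptors whose ratio changed lay next to each other in the genome more often than chance would give. There were 13 adjacent pairs changed in one direction, against a mean of 5.36 in 10000 permuted orders (one-sided permutation p = 0.002), such as Olfr1277 and Olfr1278, Olfr488 and Olfr490, and Olfr1054 and Olfr1056. Close relatives often lie side by side, so neighbours that respond together or probe sets that share signal could each explain this.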
